A study of Drosophila melanogaster with 20 samples.

How the data were processed

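The series holds 20 Agilent 1-colour arrays of 1 design, from Drosophila larvae. Per the labels' protocols, total RNA of sorted class IV neurons or whole body walls was amplified with amino-allyl nucleotides and coupled to Cy3, with 3 to 5 replicates per group; they are called independent there, without saying what was separate. P-values therefore measure the spread between these samples. Groups and replicate numbers were taken from the sample titles, and slide and position from the labels. Wild type/deficiency body walls were on slide 14, the other body walls on slide 17, and neurons on slides 2 and 3. Each slide was scanned at its own time, so scan and slide are the same batch. Within each slide that held 2 groups, the first position number parted the groups exactly, so position and genotype cannot be told apart.

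The scanner files hold spot intensity values on a linear scale: per the file headers, Agilent Feature Extraction 10.7.3.1 made them, and its processed signal, which the authors deposited, is already background-subtracted and can be negative. The median signal and the local background of each spot are also intensity values, per the file headers. The deposited value table holds log2 values, and the submitters' processing notes name limma without saying what it was used for. Each column of that table ranked the probes as the array's raw median signal did (rank correlation 1), and its sorted columns differed from their mean by at most 0.09, so it is a quantile-normalized log2 signal without background subtraction that could be detected. Column medians were 7.07 to 7.09. Its direction is that of the signal, and its other processing is not given in the sources used here.

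Of 61657 probes other than controls, 430 with a non-uniformity flag on any array were left out, which kept 61227. No probe was saturated. Under the planned rule each array's processed signal was to be scaled to its 75th percentile. Because fewer probes than not were detected on many arrays, the percentile was taken over the 8311 probes well above background on all 20 arrays, a change made after detection was seen, with all probes as an alternative. Signals were scaled first, then floored at the highest of the arrays' lowest detected signals within a fit, then taken to log2. The floor was a scaled signal of 71.6 for neurons and 200 for body walls and for all 20 arrays, which left 7.27 and 5.79 log2 units below the 75th percentile. Falls below that range are understated. Values set to the floor lose their spread, which p-values then do not measure. Where a probe was not well above background on any array of a group, the fold is a lower bound: the brighter group's mean log2 signal against the mean, over the dim group's arrays, of the higher of the array's lowest detected signal and the probe's own.

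Probes well above background on at least 3 arrays of a group compared were tested with limma 3.58.1 (lmFit and eBayes, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The neuron comparison used the 10 neuron arrays, each body wall comparison all 10 body wall arrays, and the comparisons across tissues all 20. Random blocks used duplicateCorrelation (statmod 1.5.0). Values per array came from Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The number of arrays limits the precision.

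The files used here do not pair probe IDs with genes, and 0 probe IDs were found in the reference gene table. Each probe was therefore its own unit. The planned values of the path transcript, the genes next to it and the fixed gene lists were not analysed here, nor was the mean of a gene's probes. The path transcript could thus not serve as a check of the labels. Named probes follow a rule set before the data were examined, shortened for lack of names: among called probes whose groups' arrays did not overlap, the 2 largest rises and 2 largest falls. For the body wall mutant a probe had to pass against both controls and was ranked by its smaller difference. For the difference between tissues the neuron groups had to be apart. Differences with a group at the floor were ranked as fitted, so which are largest is not settled.

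The fit was tested on simulated arrays with the probes' own means and SDs and 200 changed probes per comparison. Each probe had the same mean before the change and the same SD in all groups, while the real groups differed in spread. More probes passed in the real comparisons given here, which eases the adjusted threshold. The shares below therefore hold for the simulated setting and do not give the recovery or the false calls of the real comparisons. For neurons (34519 probes) 2%, 12%, 46% and 40% of 2-, 4-, 8- and 16-fold changes were recovered, with 9.1% false calls. For path/deficiency against wild type/path (26510 probes) the shares were 4%, 34%, 60% and 72%, with 12.4% false calls, and against wild type/deficiency (29138 probes) 14%, 46%, 54% and 66%, with 2.2% false calls. Between wild type neurons and body walls (33937 probes) the shares were 18%, 42%, 50% and 70%, with 8.2% false calls. The difference of the path effects between tissues was not simulated.

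Alternatives set before the data were examined were normexp background correction (offset 50, on the median signal because the mean signal planned for it was not used here), quantile normalization, both together, the deposited values, other filters, array weights, a trended robust fit, a 2-fold minimum, blocks, other control groups and leaving out each array. Scaling over all probes, a median floor, array brightness as a covariate, all tests on tissue-enriched probes, and the correlation of path effects between tissues were chosen after seeing the data. No arrays held identical values; the highest correlation between arrays of a group was 0.98.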

Results

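Gene expression was measured in Drosophila melanogaster larvae of the 3rd instar with mutations in path (pathetic), a gene for a membrane transporter of the SLC36 family. RNA came from 2 sources. Class IV dendritic arborization neurons, sensory neurons of the body wall with large branched dendrites, were marked with ppk and isolated by fluorescence-activated sorting. The other source was the whole opened body wall. Amplified RNA of each sample was labelled with Cy3 and hybridised to its own array, which gave 20 arrays in 5 groups. Sorted neurons were wild type (n = 5) or path mutant (n = 5). Body walls were path mutation over deficiency (n = 4), wild type over deficiency (n = 3) or wild type over path mutation (n = 3); a deficiency is a chromosome that lacks a segment. Each array had 61227 usable probes with 1 spot each. The files used here do not pair the probe IDs with genes, so results are given for probes, with at most 2 IDs that rose and 2 that fell in each comparison.

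The share of probes well above background was 42.0% to 59.0% on the wild type neuron arrays and 38.4% to 54.8% on the path neuron arrays. It was 49.98% to 54.6% for wild type/deficiency body walls, 45.1% to 48.0% for wild type/path and 41.2% to 46.9% for path/deficiency replicates 1 to 3. Path/deficiency replicate 4 was dim, with 22.6% of probes well above background. Its 75th percentile signal over the 8311 probes detected on all 20 arrays was 1551, against 9930 to 17564 on the other body wall arrays. Before background correction, the negative control spots had a median signal of 209 to 405 on body wall arrays and 21 to 28 on neuron arrays. The scanner software's subtraction left 41.2% to 74.9% of body wall probes and 4.99% to 25.7% of neuron probes at or below 0.

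Arrays separated by tissue and, within neurons, by genotype. The first principal component held 54.3% of the variance and parted neurons from body walls, and the second held 15% and parted path neurons from wild type neurons. The median correlation across probes was 0.93 between wild type neuron arrays, 0.82 between path neuron arrays and 0.70 between arrays of the 2 genotypes. Path neuron arrays correlated less with body wall controls (mean r per array 0.45 to 0.55) than wild type neuron arrays did (0.64 to 0.66). Within groups, the median SD of a probe was 1.18 log2 units among path neurons and 0.67 among wild type neurons. It was 0.74 among path/deficiency body walls, 0.41 among wild type/path and 0.26 among wild type/deficiency.

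**Figure D1:**
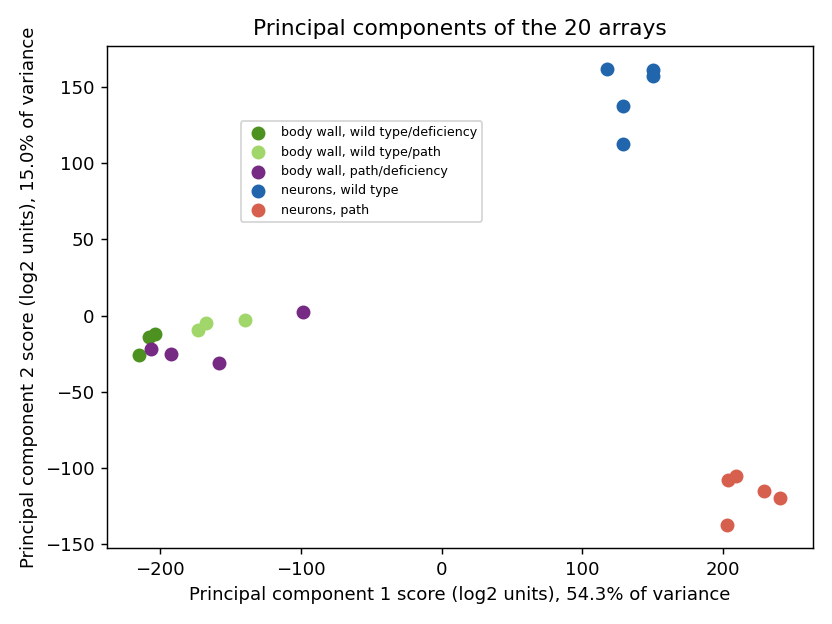
Scores of the 20 arrays on the first principal component (54.3% of variance) and the second (15%), in log2 units, with 1 point per array coloured by group. Neurons and body walls lie apart on the horizontal axis, and the 5 path neuron arrays lie apart from the 5 wild type neuron arrays on the vertical axis.

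The comparison of sorted neurons asks which transcripts differ in class IV neurons that carry path mutations. Probe ft05026 had a log2 signal of 16.11 ± 0.35 (SD, n = 5) in path neurons and lay at the floor of 6.16 on all 5 wild type arrays, a log2 difference of 9.94 (SE 0.23; limma adjusted p = 1.69e-08). It was well above background on 5 path arrays and 1 wild type array. Probe fu02555 was higher in path neurons by 9.90 (SE 0.71; limma adjusted p = 6.57e-06), with 16.66 ± 1.31 (SD, n = 5) against 6.76 ± 1.10 (SD, n = 5). Probe ft03595 fell by 8.58 (SE 0.41; limma adjusted p = 5.41e-07), from 15.06 ± 0.57 (SD, n = 5) in wild type to 6.47 ± 0.70 (SD, n = 5) in path neurons, where 1 of 5 arrays measured it above background. Probe fe04320 fell by 7.51 (SE 0.63; limma adjusted p = 2.07e-05), from 13.95 ± 1.38 (SD, n = 5) to 6.44 ± 0.62 (SD, n = 5), with 2 path arrays above background. Where a group lay at the floor the difference is understated, so the order of such probes by size is not known. The floor hides all spread of ft05026 in wild type neurons and part of the spread of the other named probes. The SE and p do not measure spread hidden in this way.

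**Figure D2:**
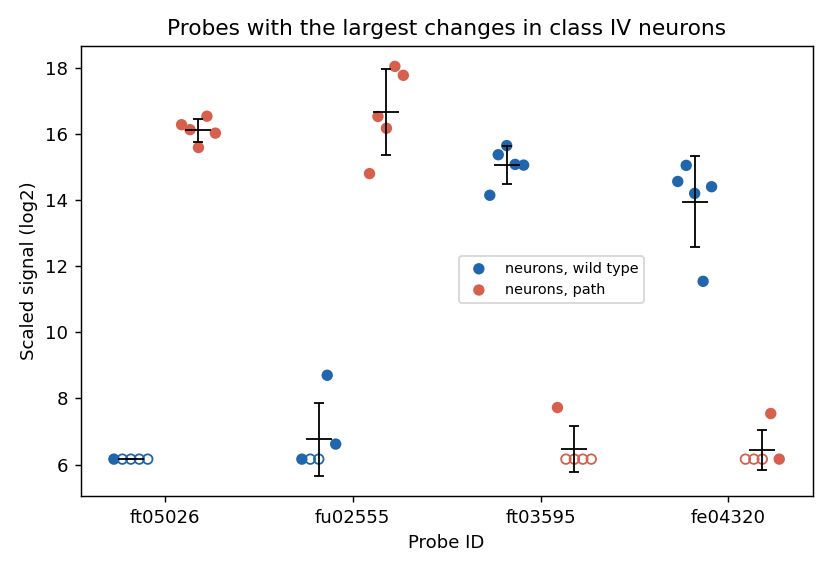
Scaled log2 signal on each neuron array for the 2 named probes that rose and the 2 that fell. Filled points are well above background, open points are not, and bars give the mean and SD of 5 arrays. The path arrays lie at 14.80 or above for fu02555 and the wild type arrays at 8.70 or below.

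In neurons, 6257 of 34519 tested probes passed an adjusted p of 0.05, of which 3379 rose and 2878 fell in path neurons. The median absolute log2 difference of the called probes was 3.06. The groups' arrays did not overlap for 4630 called probes; over all tested probes 14.7% did not overlap, against 0.79% by chance. Of the rises, 3103 were well above background on all 5 path arrays, and 319 of these on no wild type array. Of the falls, 2767 were well above background on all 5 wild type arrays, and 114 of these on no path array. On all 6 control body wall arrays, 90.6% of the falls were well above background, against 49.4% of the rises and 65.2% of all tested probes. Conversely, 21% of the rises, 3.5% of the falls and 17.3% of tested probes were above background on no control body wall array. Most falls were detected on all 5 wild type neuron arrays, while the tested probes include dim ones. Probes as well detected in wild type neurons were not counted apart. These shares therefore do not part signal strength from expression shared with body walls.

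Both genotypes were present on each neuron slide. With slide as a block 6874 probes passed, within slide 2 (4 wild type and 3 path arrays) 5189, and within slide 3 (1 wild type and 2 path arrays) 2351, where the single wild type array is assumed to vary like the others. The balance of rises and falls depended on the scaling. The median difference of all tested probes was 0.13 log2 units in the main values, 0.52 with normexp background correction and -0.21 in the authors' deposited values, and rises made up 54.0%, 69.3% and 43.9% of calls. Falls also outnumbered rises with quantile normalization (4776 against 3409), with normexp and quantile normalization (5026 against 3881) and with scaling over all probes (3806 against 2878).

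**Figure D3:**
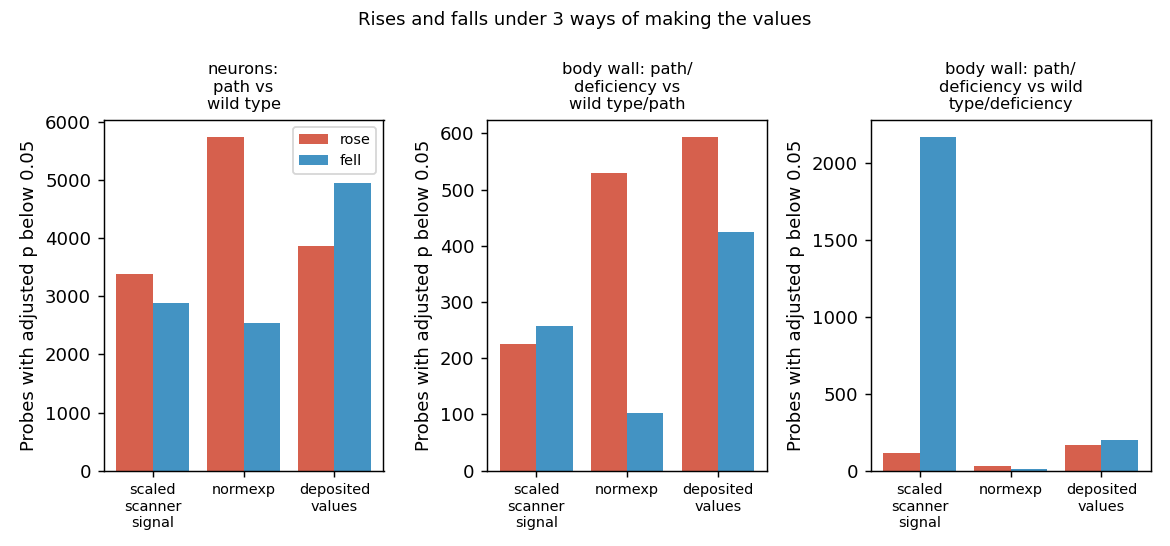
Number of probes with an adjusted p below 0.05 that rose (red) or fell (blue) in the path mutant, for the scaled scanner signal, normexp background correction and the authors' deposited values. In neurons, of these 3 settings, falls outnumber rises with the deposited values (4948 against 3869), and against wild type/deficiency the 2168 falls of the scaled scanner signal drop to 9 with normexp.

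The body wall comparisons ask what a path mutation over a deficiency changes in the whole tissue, with each heterozygous control shown apart. Probes fc17871 and fc17870, whose numbers are consecutive, were higher in path/deficiency body walls than in both controls. For fc17871 the log2 signal was 14.29 ± 0.50 (SD, n = 4) in the mutant, 10.31 ± 1.62 (SD, n = 3) in wild type/path and 9.78 ± 1.29 (SD, n = 3) in wild type/deficiency. Its log2 differences were 3.98 (SE 0.77; limma adjusted p = 0.038) and 4.52 (SE 0.79; limma adjusted p = 0.0207). For fc17870 they were 3.98 (SE 0.71; limma adjusted p = 0.0303) and 4.62 (SE 0.72; limma adjusted p = 0.0144), from 15.34 ± 0.46 (SD, n = 4) in the mutant. Probe fv00703 fell by 6.81 (SE 0.94; limma adjusted p = 0.014) against wild type/path and fell by 5.55 (SE 0.96; limma adjusted p = 0.0204) against wild type/deficiency, to 8.93 ± 1.32 (SD, n = 4). Probe fc22449 fell by 6.55 (SE 1.06; limma adjusted p = 0.0241) and fell by 5.21 (SE 1.08; limma adjusted p = 0.0309), to 8.87 ± 0.91 (SD, n = 4). The calls depended on single arrays, while the differences kept their direction and, with 1 array left out, most of their size. Leaving out each array gave log2 differences against wild type/path of 3.11 to 4.72 for fc17871, 3.26 to 4.61 for fc17870, -7.31 to -6.32 for fv00703 and -7.44 to -5.41 for fc22449. Against wild type/deficiency they were 3.998 to 5.24, 4.10 to 5.36, -6.52 to -4.65 and -5.86 to -4.16. Over all settings the smallest differences, in the same order, were 1.74, 2.55, -1.09 and -1.08 against wild type/path. Against wild type/deficiency the smallest were 1.74, 2.55, -0.50 and -0.37. Against wild type/path, fc17871 lost its call in 10 of 19 settings and fc17870 in 7 (limma adjusted p up to 0.46), fv00703 in 3 of 18 and fc22449 in 6. Against wild type/deficiency fc17871 lost it in 5 of 19, fc17870 in 4, and of 18 settings fv00703 in 5 and fc22449 in 8 (limma adjusted p up to 0.638). Without wild type/path replicate 2 the limma adjusted p against that control was 0.13 for fc17871, 0.118 for fc17870, 0.0886 for fv00703 and 0.106 for fc22449. Without its replicate 3 it was 0.082, 0.0707 and 0.0501 for fc17871, fc17870 and fc22449. Without path/deficiency replicate 1 it was 0.0702 and 0.0646 for fc17871 and fc17870, and without replicate 3 it was 0.0861, 0.0733 and 0.0664 for fc17871, fc17870 and fc22449. Without replicate 4 it was 0.0567 for fc17871. Against wild type/deficiency it was 0.106, 0.0774, 0.1 and 0.113 for fc17871, fc17870, fv00703 and fc22449 without wild type/deficiency replicate 2. For fc22449 it was 0.12 without wild type/deficiency replicate 1 and 0.0647 without path/deficiency replicate 2. Without path/deficiency replicate 3 it was 0.0509, 0.0589 and 0.0645 for fc17871, fv00703 and fc22449.

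Against wild type/path, which shared slide 17 with the mutant, 484 of 26510 probes passed, of which 226 rose and 258 fell. Rises made up 46.7% of calls, 83.7% with normexp and 58.3% in the deposited values, and 1018 probes passed in the deposited values. Leaving out 1 array gave 34 (wild type/path replicate 2), 257 (wild type/path replicate 3), 133 (path/deficiency replicate 1), 1290 (replicate 2), 72 (replicate 3) or 756 (replicate 4) probes.

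Against wild type/deficiency 2284 of 29138 probes passed, of which 116 rose and 2168 fell. These groups lay on different slides, so slide and genotype cannot be told apart. Rises made up 5.1% of calls, 76.9% of the 39 probes that passed with normexp and 45.1% of the 366 in the deposited values. The median difference of all tested probes was -0.43 log2 units, 0.02 with normexp and -0.05 in the deposited values. Leaving out 1 array gave 162 (wild type/deficiency replicate 1), 95 (wild type/deficiency replicate 2), 4615 (path/deficiency replicate 1), 520 (replicate 2) or 300 (replicate 3) probes.

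Against both controls in the same direction, 209 of 26267 probes passed, of which 38 rose and 171 fell. None passed in opposite directions. Both contrasts use the same mutant arrays. Independent lists of these sizes would share 1 rise and 16.7 falls. Arrays simulated without effects shared a median of 0 probes and at most 1 over 50 simulations. Without effects few probes can pass in either contrast, so this count does not test the overlap of lists as long as the real ones. With the 4 mutant arrays divided between the contrasts in the 6 ordered ways, 3 to 230 probes were shared. The log2 differences against the 2 controls correlated at 0.69 across probes, which are not independent, against 0.43 in the simulation and 0.13 to 0.54 with the mutant arrays divided. Their covariance was 0.52, against 0.11 in the simulation. Rises made up 18.2% of these, 76.2% of the 21 probes that passed with normexp and 53.1% of the 147 in the deposited values. Leaving out 1 array gave 50, 28 or 138 (wild type/deficiency replicates 1, 2 and 3), 21 or 83 (wild type/path replicates 2 and 3), or 96 or 37 probes (path/deficiency replicates 1 and 3).

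The controls were also set against each other, as the background of the body wall comparisons. Probes fc08145 and fc25542 were higher in wild type/deficiency than in wild type/path, by 4.33 (SE 0.58; limma adjusted p = 0.0229) and 3.99 (SE 0.63; limma adjusted p = 0.0335) log2 units. Without wild type/deficiency replicate 1 or 2 or wild type/path replicate 1, the limma adjusted p was 0.0711, 0.0974 and 0.11 for fc08145 and 0.0585, 0.0817 and 0.146 for fc25542, and 0.0811 for fc25542 without wild type/path replicate 3. Leaving out each array gave differences of 3.88 to 4.75 for fc08145 and 3.17 to 4.42 for fc25542, and over all 17 settings of each the adjusted p went up to 1. Probes ft02303 and fu05014 were not well above background on any wild type/deficiency array. Their fitted log2 differences were -4.71 and -4.46 with the floor set by the dimmest array (limma adjusted p = 0.00167 for both), and -5.84 and -5.86 in the deposited values. The floor hides their spread in wild type/deficiency, so the p of the fitted differences does not measure it. Over 16 settings of each, ft02303 and fu05014 differed by -7.37 to 0 and by -7.12 to 0, and each lost its call in 2. Against each wild type/deficiency array's own lowest detected signal, which lay below the fit's floor, they were at least 182.6-fold and 153.5-fold lower on the background-subtracted scale. In all, 190 of 28961 probes passed, of which 175 were higher in wild type/deficiency, and the groups lay on different slides. With normexp 41 probes passed and in the deposited values 70, and the share higher in wild type/deficiency was 92.1% in the main values, 75.6% and 75.7%. Leaving out wild type/deficiency replicate 1, 2 or 3 gave 12, 19 or 678 probes, and leaving out wild type/path replicate 1 gave 7.

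Wild type neurons were compared with both heterozygous body wall controls to see which transcripts are enriched in class IV neurons. Probes fc24275 and fc24276 were higher in neurons by 6.91 (SE 0.44; limma adjusted p = 9.12e-10) and 6.86 (SE 0.48; limma adjusted p = 3.07e-09). Probes ft05854 and fr00231 fell by 10.71 in neurons relative to body wall (SE 0.33 and 0.41; limma adjusted p = 2.8e-14 and 6.14e-13), with neurons at the floor of 7.64 on all 5 arrays and body walls at 18.36 ± 0.18 and 18.35 ± 0.18 (SD, n = 6). They were nevertheless well above background on 3 and 4 of the 5 neuron arrays, with signals at or below the floor of this fit. The floor hides their spread in neurons, so the SE and p do not measure it, and the falls are understated. Of 33937 probes, 16018 passed, of which 4117 were higher in neurons and 11901 in body walls. Tissue, slide and control genotype cannot be told apart here. With slide as a random block 15141 probes passed. Probes higher in neurons were 25.7% of calls, 13.8% with normexp and 54.9% in the deposited values, and the median difference of all tested probes was -0.30, -1.32 and 0.31.

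The difference between the path effect in neurons and the path effect in body walls was tested in a model of all 20 arrays. Probe ft01724 averaged 14.01 ± 0.49 (SD, n = 5) in path neurons and lay at the floor of 7.64 in wild type neurons. It averaged 8.39 ± 0.97 (SD, n = 4) in path/deficiency body walls against 12.16 ± 0.22 and 12.13 ± 0.12 (SD, n = 3 each) in the controls. Its effects differed by 10.13 log2 units (SE 0.45, limma adjusted p = 6.8e-11). The floor hides its spread in wild type neurons, so the SE and p do not measure it. For ft01330 the difference was 11.21 (SE 0.97; limma adjusted p = 2.25e-07). For fu05248 and fe05564 the neuron effect lay below the body wall effect, with differences of -6.65 (SE 0.68; limma adjusted p = 1.73e-06) and -6.56 (SE 0.48; limma adjusted p = 2.9e-08). In total 6770 of 36746 probes differed, with the neuron effect above the body wall effect for 4621 and below it for 2149. Of the 6770, 4304 were also called in the neuron comparison with the same sign. With slide as a random block 6559 probes differed, with array weights 11003, with detection on every array 1431 and with scaling over all probes 42. Of 32 settings of each named probe, ft01724, fu05248 and fe05564 lost their call in 1 and ft01330 in 0. The neuron effect was the higher one for 68.3% of calls, and for 46.3% in the deposited values.

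The path effects in the 2 tissues, which share no array, correlated at 0.10 across 24916 probes (jackknife SE over arrays 0.10), with a covariance of 0.13. Among 23301 probes tested in both tissues, 4 rose in neurons and against both body wall controls and 21 fell in both, where independent lists would share 2.2 and 16.9. Another 9 rose in neurons and fell in body walls (11.5 for independent lists), and 1 went the other way (3.3).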

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

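The rules for the results below were set before the data were examined, and the named probes follow from the rule in the methods.

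A single array lay far from the others of its group in 4 of 37 groups of values tested. Chance puts about 1 in 20 groups past this limit, but that rate does not hold where arrays are set to the floor, as in 3 of the 4. Wild type neuron replicate 4 had a log2 signal of 8.70 for fu02555, with the nearest wild type array at 6.62. It also had 11.54 for fe04320, with the nearest wild type array at 14.20. Path neuron replicate 1 had 7.72 for ft03595 and path neuron replicate 4 had 7.54 for fe04320, with all other path arrays at the floor of 6.16, which by construction puts any array above the floor past the limit.

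The path effect differed between neurons and body walls for 6770 probes, by a limma test of the difference itself. Among the named probes it differed by 11.21 log2 units for ft01330 and by 10.13 for ft01724, and by -6.65 for fu05248 and -6.56 for fe05564. The first pair was higher in path neurons than in wild type neurons and lower in mutant body walls than in both controls by group means, and the second pair went the other way in neurons. Of 100 splits of the samples, 1 (the real one) gave as many probes, so chance can be excluded for the count as a whole at this number of splits. The highest of the others gave 4622 and kept the neuron groups while it regrouped body walls. The count is therefore not read as evidence on the body wall effect. Of the probes called, 6056 were also tested in neurons alone, where 4307 were called, 4304 with the same sign. The count thus rests largely on the neuron effect. Tissues lay on separate slides and were isolated in different ways. The genotypes compared also differed: path against wild type in neurons, and path over a deficiency against heterozygous controls in body walls. This leaves the tissue itself, the genotypes compared, the slide, the position on it and the isolation as open explanations.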

How the results depend on the processing

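Scaling over all probes, the median floor, the brightness covariate, every test on tissue-enriched probes and the correlation of path effects were chosen after seeing the data. Counts are probes with a limma adjusted p below 0.05; the cause of a change was not tested unless given. Of 538 settings of named probes, 469 kept direction and call, 65 kept direction but missed the threshold, 4 had a difference of 0 (control against control, scaling over all probes) and 0 reversed; in 18 more the probe was not tested. The body wall mutant's probes lost their call in 48 of 148 settings and the controls' in 16 of 66, against 5 of 324 for the other comparisons. The 4 neuron probes stayed past the threshold in all 25 settings run for each. Signal over background limits the falls, which end at the floor.

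Against wild type/path, wild type/deficiency and between controls, normexp gave 633, 39 and 41 probes, quantile normalization 1042, 359 and 308, both together 1103, 341 and 72, and the deposited values 1018, 366 and 70. Normexp left 21 against both controls. Scaling over all probes gave 0, 0 and 0 (3, 7 and 0 at an unadjusted limma p below 0.05), 0 against both controls, 14 between tissues and 42 for the difference of path effects. By construction, the 75th percentile of path/deficiency replicate 4 over all probes was 1.06, near 0. The median floor gave 391 between controls.

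Requiring detection on every array, which tests fewer probes, gave 2396 in neurons, 6 against wild type/deficiency, 4 against both controls, 33 between controls, 4391 between tissues and 1431 for the difference of path effects. Array weights gave 10256 in neurons, 5718 against wild type/path, 13568 against wild type/deficiency, 3430 against both, 2923 between controls and 11003 for the difference. They ran from 0.127 (path/deficiency replicate 4) to 13.4 (replicate 3) over all body wall arrays. The weights did not converge against wild type/path and between controls, so those counts and the count against both are not reliable. A trended robust fit gave 388 between controls, and fitting only the 2 groups 71 against wild type/path. In neurons slide 3 alone, with fewer arrays, gave 2351 and the brightness covariate 4031.

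Replicate number as a block gave 28 against wild type/path, 11 against wild type/deficiency, 3 against both and 0 between controls (4700 at an unadjusted limma p below 0.05). Residuals of arrays with the same number did not correlate throughout (-0.42 to 0.43), so a pairing by number was not seen, though so few arrays cannot exclude it. The block spends degrees of freedom. It also takes up path/deficiency replicate 4, the only body wall array of that number. The median difference against wild type/path was -0.06 with the block and -0.24 without it.

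Leaving out each array gave 4683 to 6568 in neurons, 34 to 1290 against wild type/path, 95 to 4615 against wild type/deficiency, 21 to 286 against both, 7 to 678 between controls, 14700 to 15851 between tissues and 5667 to 7500 for the difference.

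Exact permutation p-values below keep the sets of probes fixed and do not count how the sets were chosen. The shift of body-wall-enriched probes (-0.10) was 0.45 with normexp, 0.085 with the median floor, 0.59 with detection on every array and 0.15 when enriched at least 16-fold. It was -0.47 with quantile normalization and -0.24 with normexp and quantile normalization (exact permutation p = 0.0476 for both). It was -1.07 with the set chosen on path neurons and -0.45 on both genotypes. Leaving out each array gave -0.54 to 0.18. It was 0.14, 0.18, 0.09 and 0.05 without wild type neuron replicates 1 and 5 and path neuron replicates 2 and 3. The shift of neuron-enriched probes (-0.99) was -0.65 with the median floor (exact permutation p = 0.119), -0.49 with detection on every array, -2.88 when enriched at least 16-fold and -4.87 with scaling over all probes (sets of 1 and 6 probes), the last 3 at an exact permutation p of 0.00794. It was 3.65 with the set chosen on path neurons, a choice that favours a rise by construction, and 1.35 with the set chosen on both genotypes, where the cause was not tested. Leaving out each array gave -1.06 to -0.62. The correlation of path effects between tissues was 0.03 to 0.14 when leaving out each array.

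The mean of a gene's probes was not run, since genes are not named. Scaling over all probes left no body-wall-enriched set.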

Other observations

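The tests below, except the counts of other splits, were chosen after seeing the group comparisons, and the normexp test of falls after its own result was seen. Normexp, quantile normalization and leaving out an array were settings fixed before the data were examined, but their use as tests of the balance of falls was not.

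Probes enriched at least 4-fold in wild type neurons or in control body walls were chosen on odd or even replicates and scored on the other neuron arrays. Each wild type array was scored with the set it did not define, and each path array with the mean of both sets. Exact p-values regrouped these scores with the sets kept fixed, so they do not count how the sets were chosen. The 5676 and 6734 body-wall-enriched probes averaged 7.01 ± 0.97 log2 units (SD, n = 5) in wild type and 6.91 ± 0.75 (SD, n = 5) in path neurons. A fall of these probes had been anticipated and was not found in the main values: the shift was -0.10 (exact two-sided permutation p = 0.778). The score lay at the floor of 6.16 on wild type replicates 2 and 4 and path replicate 2. A fall cannot register below the floor, so this value does not exclude one. The median shift of single probes was 0.197 in the odd-replicate set and 0 in the even-replicate set. The shift of the score was -0.47 with quantile normalization and -0.24 with normexp and quantile normalization (exact p = 0.0476 for both). With normexp alone it was 0.45 (exact p = 0.357). With the set chosen on path neurons it was -1.07 (exact p = 0.0873) and on both genotypes -0.45 (exact p = 0.421), so the call depends on the scaling and a fall stays open. The tests prepared for such a fall are void in the main values, where no shift passed. Their values were 56% of the brightest 100 probes within 1 log2 unit of the median shift, a shift of 0.066 with array brightness as a covariate, and -0.37 within slide 2.

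The 1491 and 1214 neuron-enriched probes averaged 12.34 ± 0.26 (SD, n = 5) in wild type and 11.35 ± 0.22 (SD, n = 5) in path neurons, lower on 5 of 5 path arrays than on every wild type array. With the sets kept fixed, the shift was -0.99 (exact two-sided permutation p = 0.00794, the smallest that 252 regroupings can give). It was -0.905 within slide 2, and 38% of the brightest 100 probes moved within 1 log2 unit of the median shift; the median shift of the probes in the odd- and even-replicate sets was -0.87 and -0.76, and with array brightness as a covariate -1.11 and -0.87 (mean -0.989). The shifts within slide 2 (exact permutation p = 0.0571) and with the covariate argue against slide or dimmer arrays as the whole cause. Position on the slide parted the genotypes and stays open. The share of 38% cannot decide on a uniform loss of neurons. Body-wall-enriched probes, whose shift did not pass, gave 56%, so the share has no reference without a loss. Scaling stays open too. The shift was -1.03 with normexp, -0.79 with quantile normalization, -0.70 with both and -0.68 in the deposited values (exact p = 0.00794 for each). With the median floor it was -0.65 (exact p = 0.119). A set chosen on path neurons was higher in path neurons by 3.65 and a set chosen on both genotypes by 1.35 (exact p = 0.00794), and since choosing on 1 genotype favours that genotype by construction, the fall is not read as a loss of neuronal transcripts and the part played by the choice stays open.

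Falls outnumbered rises in path/deficiency body walls against wild type/deficiency. Without the dim array, path/deficiency replicate 4, 85.9% of calls fell, which argues against that array as the whole cause. With normexp, which also uses another signal, 23.1% of 39 calls fell. With quantile normalization, which keeps the scanner software's background subtraction, 62.1% of 359 fell. Among the 13091 probes well above background on every body wall array, 5 calls rose and 1 fell, and the median difference was -0.09. This was a separate fit with its own adjustment, in which 2618 probes had an unadjusted limma p below 0.05. The filter also drops probes that fell below background in the mutant. Its 6 calls are too few to show which probes carried the imbalance. The background subtraction and the scaling cannot be told apart as sources of the imbalance. Slide and genotype cannot be told apart here, and a biological effect of the mutation on this balance stays untested.

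A shared response of both tissues to loss of path is a hypothesis that these data leave open. The correlation of path effects across probes was 0.10 (jackknife SE 0.10) and 0.057 at its lowest over the scalings (0.12 at its highest), so a weak shared response and none cannot be told apart.

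Other splits of the samples were counted for each comparison, the real one included. In neurons 1 of 100 splits gave as many probes as the real 6257 (highest other 108). Between tissues 1 of 100 gave as many as the real 16018 (highest other 10737). For these counts chance can be excluded at this number of splits. Against both body wall controls 1 of 100 gave as many as the real 209 (highest other 41). Each contrast behind that count had another split at least as large, as given next, and leaving out wild type/path replicate 2 gave 21 probes. Chance is therefore not called excluded for it. Against wild type/path 2 of 35 splits gave as many as the real 484, the other being 719 with path/deficiency replicate 2 grouped with the controls. Against wild type/deficiency 2 of 35 gave as many as the real 2284, the other being 2874 with path/deficiency replicate 1 grouped with the controls. Chance cannot be excluded for these 2 counts. Between controls there are 10 splits, too few for a share under 0.05, with 190 for the real split and 0 for the highest other.

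Probes with consecutive numbers under the same prefix were called together more often than random probes. Shares are of called probes whose partner was tested. In neurons 43.8% of 4601 such probes had a partner called with the same sign, against 9.3% for a random probe. Against wild type/path the shares were 35.1% and 0.7%, against wild type/deficiency 30.7% and 7.6%, and between tissues 55.4% and 28.3%. Whether such probes share a gene is not known here, so the counts of probes are not read as counts of genes.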
